A study of Mus musculus with 25 samples.

How the data were processed

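Genomic DNA of 25 FVB mice was profiled by MSA-seq: islets of control and small-litter mice at P21 and P180 and whole pancreas of control mice at P21, with 5 mice per group. Per the labels' protocols, islets were purified by 3 rounds of hand-picking, 500 ng of DNA were digested serially with SmaI and XmaI, adaptor-ligated and amplified, and the products were sheared to 200 to 500 bp and sequenced as paired ends on an Illumina HiSeq instrument. The submitters' processing notes name FastQC 0.10.1, cutadapt and Bowtie 0.12.9 and the mouse genome build mm9. The rule by which reads were assigned to intervals, the handling of PCR duplicates and the filter that set the list of intervals are not given in the sources used here. The authors deposited 1 table of raw read counts per interval between neighbouring SmaI/XmaI sites, with no normalization. Whole-number values and totals that differ between libraries show that no scaling had been applied. The table listed 22749 intervals (22300 autosomal, 446 on X and 3 on Y), with a lowest total of 148 counts over all libraries. Amplification and shearing mean that reads are not independent molecules, and that libraries can differ in how well short and long intervals are represented. A count is a relative measure of methylation at a pair of sites, with no absolute level. Whether start positions count from 0 or 1 is not stated, and positions are given as the table gives them.

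Groups were taken from the sample labels. The litters that the mice came from are not given, so mice of a group may be siblings. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Intervals were kept by filterByExpr, libraries were scaled by the trimmed mean of M-values (TMM), and a robust quasi-likelihood model was tested with Benjamini-Hochberg adjustment at 0.05. The 20 islet libraries were fitted together with 1 mean per group (22654 intervals), and age, age within a litter group, litter size at each age and their interaction were contrasts of these means. The contrast between tissues was fitted on the 10 control P21 libraries alone (22514 intervals). The common biological coefficient of variation was 30.6% in the islet fit and 31.7% in the tissue fit. Standard errors of log2 fold changes were derived from the test statistic. CPM values were scaled by TMM over all 25 libraries, and log2 values used a prior count of 2. Scores per mouse were compared by exact permutation over 252 assignments, whose smallest two-sided p is 0.00794. Where the control P21 libraries were divided between score and contrast, each division had only 21 assignments, and that limit does not apply.

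Stretches and neighbouring pairs named under other observations were chosen after their values were seen. The other intervals named in the text were chosen by a rule fixed before the data were examined: for age and for tissue, up to 10 intervals with the largest log2 fold change in each direction among those past the threshold whose groups do not overlap, in both litter groups for age. Total counts ran from 2912624 to 10591677 with a median of 4427238. Chi-square per degree of freedom between replicates ran from 3.59 to 32.0, and the lowest correlation of log2 counts between replicates was 0.765. Libraries differed in their trend on interval length, with correlations of the deviation with length from -0.52 to 0.44. The models were tested on simulated counts with the means, library sizes and spread of the data and 200 changed intervals. These were drawn only from intervals above a floor of mean counts, so recovery at low counts was not examined. For age, 82% of the 100 intervals changed 2-fold and 99% of those changed 4-fold were recovered, with 4 false calls among 22639 intervals. With length trends added to the simulated libraries, the values for age were 51% and 95%, with 6 false calls. For the tissue comparison, 34% and 92% were recovered, with 6 false calls among 22526. For litter size at P180 the values were 53% and 94%, with 2 false calls among 22642. The simulated counts carried no structure between libraries, such as length trends, unless it was added.

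Alternatives fixed in advance were other scaling factors, no filter or a stricter one (a mean of at least 50 counts), DESeq2 1.42.0, all libraries in one fit, the replicate number as a block, autosomes only, a fold threshold, and each library left out in turn. Alternatives chosen after seeing the data were a correction for interval length (lowess, span 0.3), limma 3.58.1 voom with library quality weights, removal of 2 factors estimated from residuals, leaving out the 3 libraries with the most intervals at 0, an offset for admixed exocrine signal, contrasts of tissue against small-litter islets, and, for litter size, a block for each age and replicate number. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The reference table used here names genes on build GRCm38 and no gene annotation of mm9 was used, so intervals were not assigned to genes, and the gene list tests fixed in advance (islet endocrine, acinar, duct, endothelial, immune, mesenchymal, Hox, developmental, protocadherin, imprinted, cell cycle, insulin signalling and methylation machinery genes) were not run. Base composition was not examined, since no genome sequence was used.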

Results

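DNA methylation was surveyed in the pancreas of FVB mice by methylation-specific amplification followed by sequencing (MSA-seq). In this assay the enzyme SmaI first cuts CCCGGG sites that are unmethylated, XmaI then opens the methylated ones, and adaptors ligated to those ends allow fragments flanked by methylated sites to be amplified. A higher normalised read count of an interval therefore stands for more methylation at the sites on both of its ends, on a relative scale. Islets of Langerhans, the hormone-secreting (endocrine) part of the pancreas, were taken at postnatal day 21 (P21) or day 180 (P180). The mice had been suckled until P21 either in control litters of 9 pups or in small litters of 4 pups, a model of overnutrition in early life. Whole pancreas of control mice at P21, about 98% exocrine (the part that secretes digestive enzymes), served as exocrine tissue. Each of the 5 groups held 5 mice. The table held 22749 intervals between neighbouring sites, 61 to 3000 bp long, with positions in mouse genome build mm9. Total counts per library ran from 2912624 to 5583859 in control islets at P21, from 3140503 to 10591677 in small-litter islets at P21, from 3527467 to 5862511 in control islets at P180, from 3593928 to 7080177 in small-litter islets at P180 and from 4427238 to 7739961 in exocrine tissue. Each library was counted as 1 sample.

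The first comparison asked how the methylation of exocrine tissue differed from that of islets in control mice at P21. Counts differed at 1818 intervals that were higher and 3158 that were lower in exocrine tissue, of 22514 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 5 per tissue). The differences on the lower side were larger: 532 intervals were over 4-fold lower in exocrine tissue and 45 were over 4-fold higher. All exocrine libraries lay on one side of all control P21 islet libraries at 1189 of the higher and 1757 of the lower intervals. Chance gives 0.794% of intervals not chosen for a difference, in either direction. The intervals counted here were called in the same libraries, which favours separation, so that share is no measure for them. Among the intervals higher in exocrine tissue, chr6:146581789-146583191 rose from 0.756 CPM ± 0.372 in islets to 11.3 ± 3.67 in exocrine tissue (SD, n = 5 each), a log2 fold change of 3.88 ± 0.45 (SE, adjusted p = 3.82e-05, edgeR). The interval chr2:118519375-118519954 had 14.0 CPM ± 5.39 in islets and 90.9 ± 19.3 in exocrine tissue, a log2 fold change of 2.65 ± 0.24. At chr8:111345623-111346858 the values were 5.06 CPM ± 1.15 and 35.7 ± 5.25, a log2 fold change of 2.78 ± 0.24. The other 7 intervals that the selection rule took on this side, on chromosomes 1, 4, 11, 13, 18 and 19, had log2 fold changes from 2.60 to 3.17. Some islet means on this side rest on few counts, which leaves the size of those fold changes poorly determined. The control P21 islets held 14 counts in all at chr6:146581789-146583191 and 9 at chr19:3204050-3205811, against 99 at chr8:111345623-111346858 and 288 at chr2:118519375-118519954. Control P21 replicate 3 had 0 at chr13:5328185-5330811 and chr1:172416585-172417444.

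On the side that was higher in islets, the largest difference fell on a pair of adjoining intervals of chromosome 2. There chr2:28764624-28764747 had 20.3 CPM ± 12.2 in islets and 0.173 ± 0.164 in exocrine tissue, and chr2:28764747-28765073 had 17.0 ± 9.16 and 0.207 ± 0.216 (SD, n = 5 each). These exocrine means rest on 5 and 6 counts over the 5 exocrine libraries, so the size of the fold change is poorly determined, although the islet libraries held at least 25 and 28 counts each. The interval chr14:79125036-79125490, with 51 exocrine counts in all, had 32.1 CPM ± 12.9 in islets and 1.85 ± 1.11 in exocrine tissue, a log2 fold change of -4.13 ± 0.43 (SE, adjusted p = 1.53e-05, edgeR). The other 7 intervals taken on this side, on chromosomes 1, 5, 7, 9, 10 and 11, had fewer than 20 exocrine counts each, and their islet means ran from 4.59 to 22.0 CPM. Intervals lower in exocrine tissue were short, with a median length of 441 bp against 1168 bp for all intervals tested, and intervals over 4-fold lower had a median of 224 bp. In the shortest of 10 length classes the median log2 fold change between tissues was -1.10. With each library's trend on interval length removed, an alternative chosen after seeing the data, 2679 intervals were higher and 2663 lower in exocrine tissue.

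**Figure D1:**
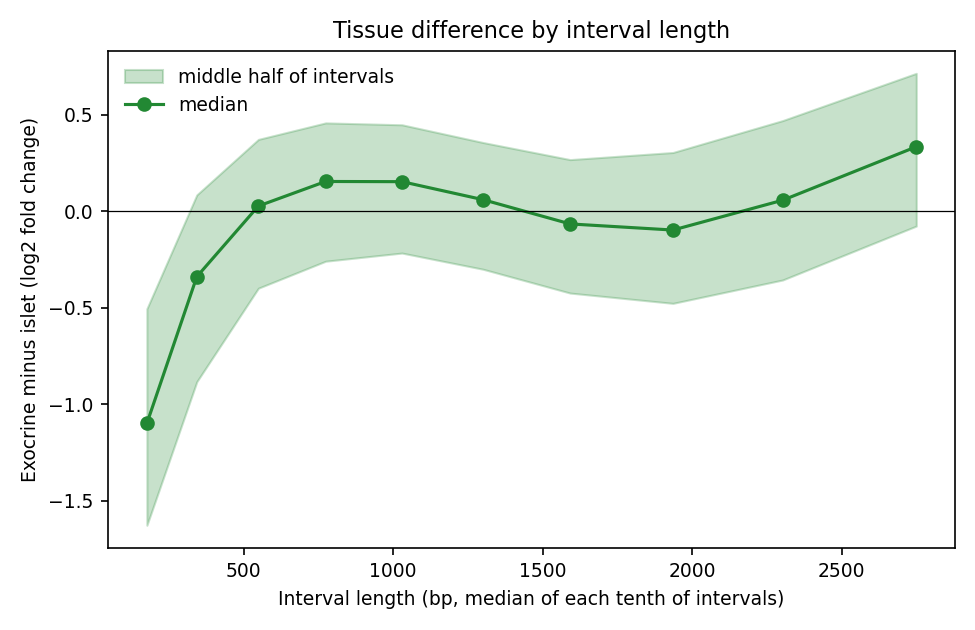
Difference between exocrine tissue and islets of control mice at P21 (log2 fold change, vertical axis) against interval length (bp, horizontal axis), for 10 classes of the tested intervals by length. Points join the medians and the band spans the middle of the distribution from the 25th to the 75th percentile; the median of the shortest class was -1.10 and that of the longest was 0.34.

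The second comparison asked which intervals changed with age in islets, from P21 to P180. With both litter groups averaged, 44 intervals gained counts and 4 lost counts at P180, of 22654 tested (edgeR quasi-likelihood test, adjusted p under 0.05, 20 libraries). The change had the same sign in control and in small-litter mice at all 48. Changes were moderate: the median log2 fold change was 0.76 among the increases and -0.71 among the decreases, and 12 increases and 1 decrease exceeded 2-fold. Ages did not overlap in either litter group at 13 of the increases and 2 of the decreases. Chance gives 0.00315% of intervals not chosen for a difference, in either direction. The 48 were called in the same libraries, which favours separation, so that share is no measure for them.

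The largest increase that the rule took was at chr11:94247192-94247996, from 5.93 CPM ± 2.09 to 18.7 ± 10.9 in control mice and from 5.40 ± 2.53 to 15.6 ± 4.58 in small-litter mice (SD, n = 5 each). Its log2 fold change was 1.61 ± 0.27 (SE, adjusted p = 0.0153, edgeR), and exocrine tissue had 32.3 CPM ± 8.61. At chr8:111345623-111346858, already named for its difference between tissues, control mice went from 5.06 CPM to 13.6 and small-litter mice from 6.30 to 14.4, a log2 fold change of 1.33 ± 0.21 (adjusted p = 0.0153). The intervals chr17:86723659-86724949, chr4:154547184-154548292 and chr7:114692369-114693781 rose by 1.17 ± 0.23, 1.11 ± 0.19 and 1.06 ± 0.17 on the log2 scale. The first of these missed the threshold in 15 of 20 refits with 1 library left out (adjusted p up to 0.111), the others in none. Smaller increases with narrower errors were seen at chr17:87730749-87731659, where control mice had 44.5 CPM ± 6.94 at P21 and 78.6 ± 23.4 at P180, and at chr19:10305041-10305784, where they had 96.2 ± 9.40 and 149 ± 35.2. The log2 fold changes of these intervals were 0.76 ± 0.12 and 0.66 ± 0.10 (both adjusted p = 0.0114). Further increases were taken by the rule at chr17:34793798-34794698, chr11:115865265-115866405 and chr10:70323018-70323796, with log2 fold changes of 0.79, 0.79 and 0.73, and missed the threshold in 9, 0 and 4 of those 20 refits. The decreases were at chr15:100525232-100526953, which went from 31.9 CPM ± 8.12 to 15.0 ± 5.19 in control mice and from 30.2 ± 6.46 to 18.8 ± 2.15 in small-litter mice, and at chr10:61519325-61520904, from 30.3 ± 3.28 to 19.5 ± 3.32 and from 35.3 ± 4.82 to 25.1 ± 2.82. Their log2 fold changes were -0.88 ± 0.17 and -0.55 ± 0.10, and they missed the threshold in 3 and 2 of the refits.

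**Figure D2:**
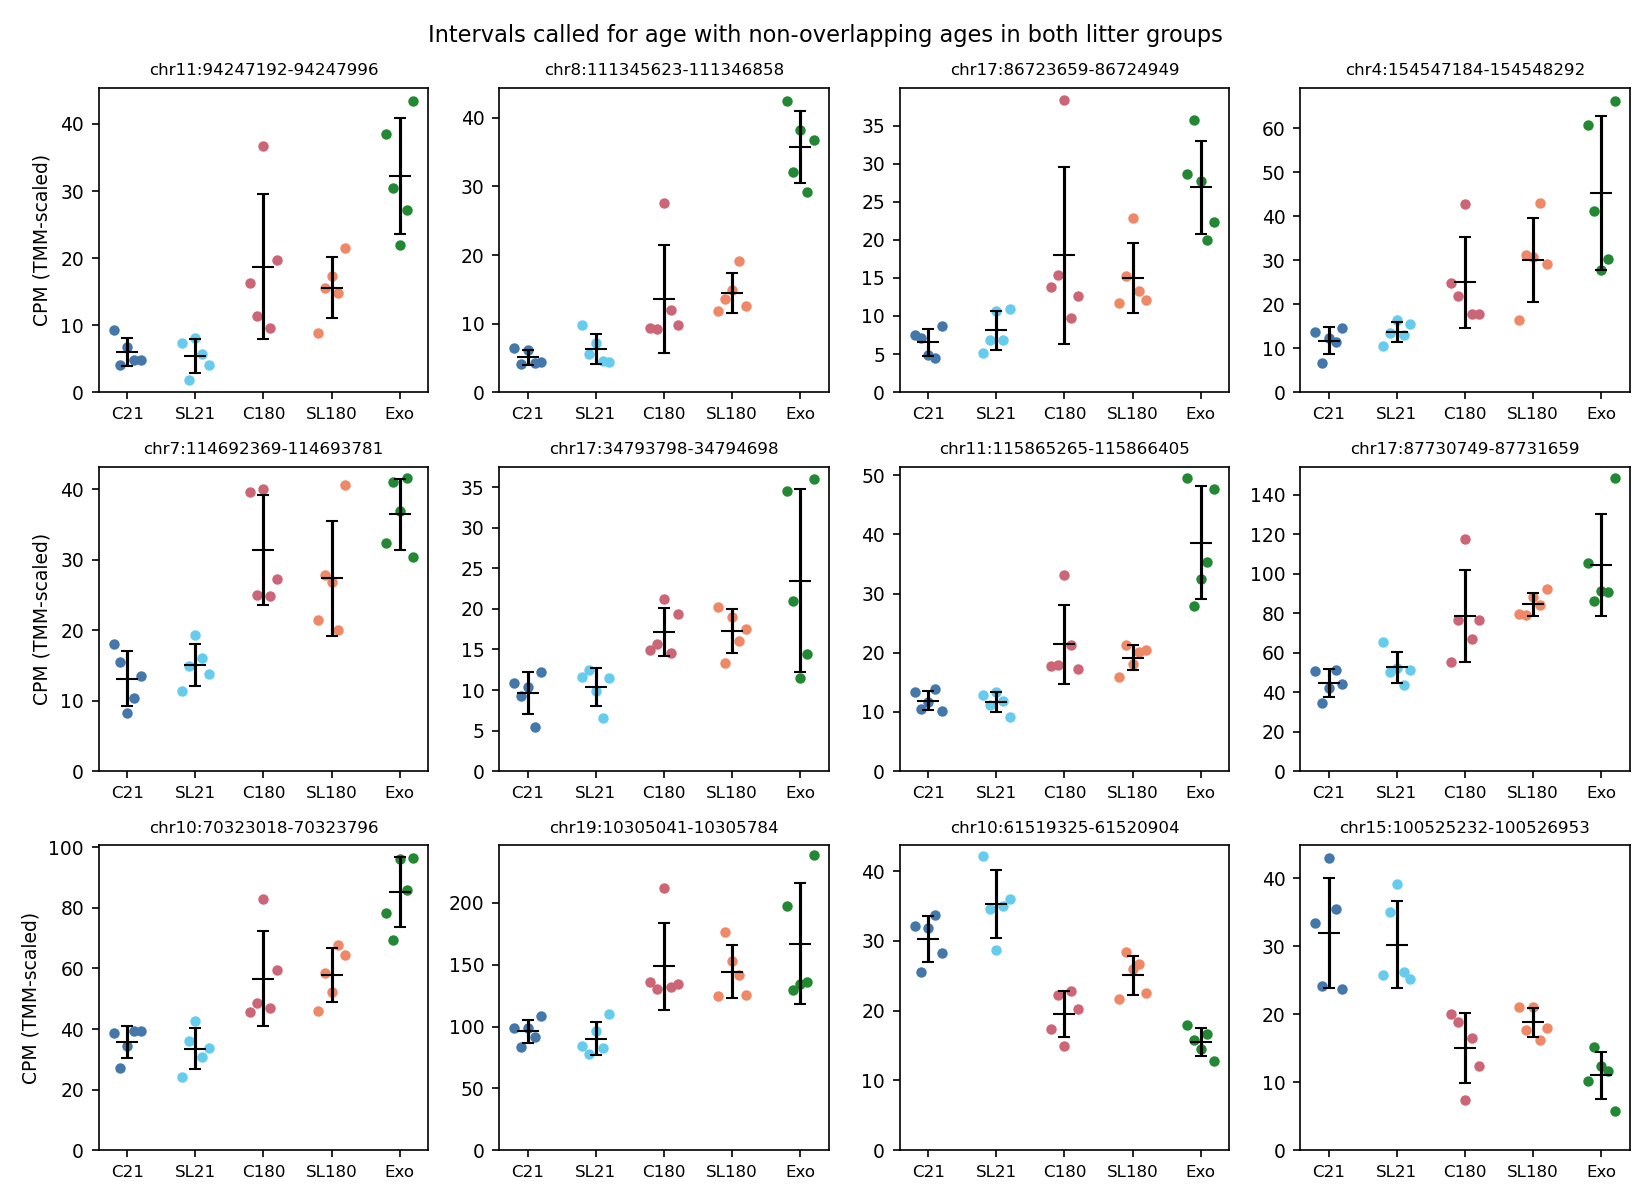
Normalised counts (CPM, vertical axes) of the 12 intervals called for age that the selection rule took, 1 panel per interval with its mm9 position. Points are mice, with the mean and SD of 5 per group, for islets of control (C) and small-litter (SL) mice at P21 and P180 and for control exocrine tissue at P21 (Exo); P180 islets lie between P21 islets and exocrine tissue on average in every panel.

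Within a litter group alone no interval passed the threshold. In control mice 1051 intervals and in small-litter mice 1174 had an unadjusted p under 0.05, where 1133 are expected with no change (edgeR). DESeq2 called 16 and 0 intervals and limma voom with library weights 2 and 0. For both groups averaged, 2167 intervals had an unadjusted p under 0.05. The number of age calls depended on single libraries: it was 16 without small-litter P180 replicate 5, 19 without control P21 replicate 3, 21 without small-litter P180 replicate 4, 25 without small-litter P21 replicate 4, 27 without small-litter P180 replicate 3 and 29, 30, 31 and 31 without small-litter P21 replicate 1, control P21 replicate 4, small-litter P21 replicate 2 and small-litter P180 replicate 2. It was 5, all increases, without the 3 libraries that had the most intervals at 0 counts (chosen after seeing the data), and 70 increases with 37 decreases once length trends were removed.

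The study's title names a shift of the ageing islet toward the exocrine pattern, so the age change was set against the difference between tissues. Of the 43 increases that could be tested for tissue, 42 were higher in exocrine tissue and 38 were called so, where independent lists would share 3.39, a value that leaves out the libraries common to both contrasts. None was called lower. All 4 decreases were lower in exocrine tissue, and 3 were called so. At chr8:111345623-111346858 and chr2:118519375-118519954 islets at P180 had intermediate values, the second with 39.7 CPM in control and 38.0 in small-litter mice. On the scale from the P21 islet mean to the exocrine mean, the P180 islet mean of the 48 intervals lay at a median of 52.8%, and 8 of the 48 lay outside that scale. Control islets at P21 enter both contrasts. In simulated unchanged groups against these libraries, 33 to 41 of the 43 strongest age increases were higher in exocrine tissue (mean 37.6 over 20 simulations). A mean of 0 were called so, and the highest number of age calls was 0. The simulated groups held no difference between tissues, so they show what sharing does to the sign but not to the number of calls. With the P21 control libraries divided between the contrasts, 35 to 43 of the 43 strongest increases were higher in exocrine tissue and 25 to 31 were called so over 10 divisions, in which 0 to 3 increases were called for age. The simulations with control mice alone gave a correlation of 0.512 between the control age change and the tissue difference over all intervals, and the observed value was 0.517. The covariance was 0.151 against 0.0638 in the simulations, a difference of 0.0870. With the control libraries divided, the covariance ran from -0.0913 to 0.148 over 10 divisions (median 0.0802) and was negative in 3, so its sign depended on which control libraries were used. With an offset for the share of exocrine signal read in each library, an alternative chosen after seeing the data, no interval was called for age. The median absolute log2 fold change of the 48 intervals was then 0.53 (median SE 0.14), where it had been 0.76 (0.14), so the calls ended through smaller changes, not through a wider error. The first form of the offset, from the mean of both share readings, left 0.38 and also 0 calls. The 48 intervals were chosen for their age change in these same libraries, which favours a remaining difference. The offset in turn takes out any shift toward exocrine tissue, also one of the islet cells themselves. Whether any change goes beyond admixture was therefore not settled.

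**Figure D3:**
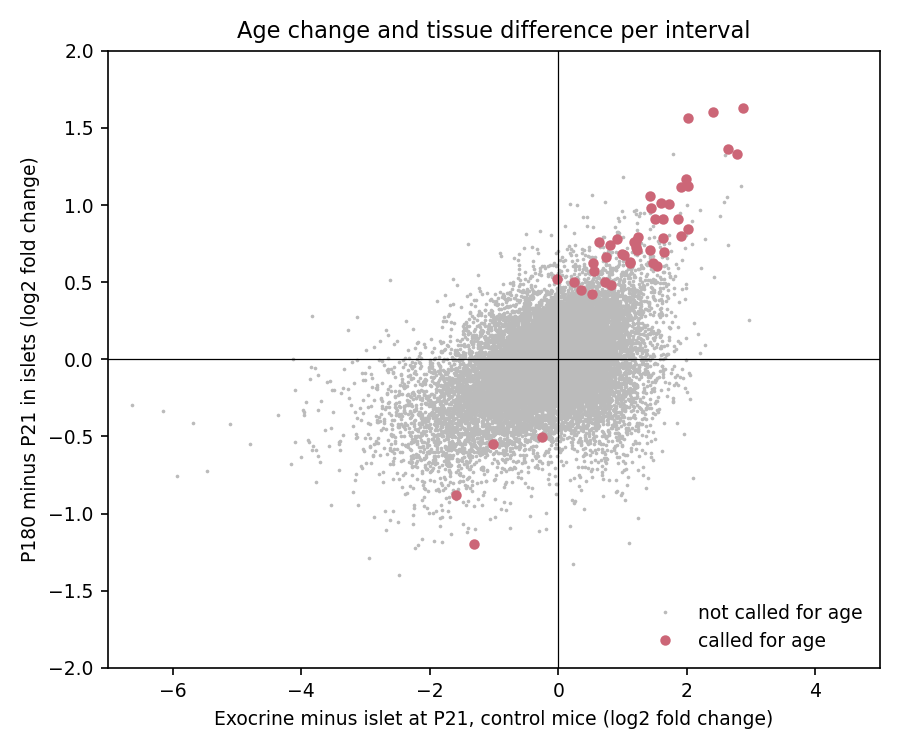
Log2 fold change of islets from P21 to P180, averaged over both litter groups (vertical axis), against that of exocrine tissue over islets in control mice at P21 (horizontal axis), 1 point per interval. Red points are intervals called for age; 42 of the 43 increases lie to the right of 0 and all 4 decreases to the left.

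The age change of small-litter mice shares no library with the contrast between tissues and was therefore the planned test of direction. Of 4928 intervals that differed between tissues, 74.0% changed toward the exocrine level with age in small-litter mice. Counts rose at 67.9% of the 1770 exocrine-higher intervals and fell at 77.5% of the 3158 exocrine-lower ones. This share was not beyond what other divisions of the same mice gave, since 9 of 100 divisions of the 10 small-litter libraries into ages, the true one included, reached it. In control mice, whose P21 libraries enter both contrasts, the share was 83.2%, and with these libraries divided it ran from 35.2% to 86.4% over 10 divisions (median 73.2%). Exocrine tissue was also set against small-litter P21 islets, an alternative chosen after seeing the data. That contrast shares no library with the age change of control mice, and 81.3% of its 3585 intervals changed toward exocrine. Other divisions of the mice were not fitted for this value. Over all intervals, 65.1% had the same sign in control mice, where simulated unchanged groups against the shared libraries gave 67.2%.

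Per mouse, a tissue score was taken as the mean log2 count of exocrine-higher intervals minus that of exocrine-lower intervals. Exocrine libraries scored 2.23 ± 0.19 (SD, n = 5). Islets scored 0.17 ± 0.39 at P21 and 0.50 ± 0.35 at P180 in small-litter mice, a difference of 0.33 within the spread between mice (two-sided exact permutation p = 0.190, n = 5 per age). In control mice the scores were -0.05 ± 0.50 and 0.41 ± 0.52, a difference of 0.45 (two-sided exact permutation p = 0.206, n = 5 per age). The control P21 libraries helped to choose the intervals, which lowers their own score, and with these libraries divided the median difference was 0.36 (median two-sided exact permutation p = 0.548, 21 assignments per division). With so few assignments this p can hardly fall below 0.05. Control P180 replicate 3 scored 1.31, above the other 4 mice of its group, which lay between 0.05 and 0.33, and so raised the difference of 0.45 in control mice. Without this replicate 34 intervals were called for age.

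**Figure D4:**
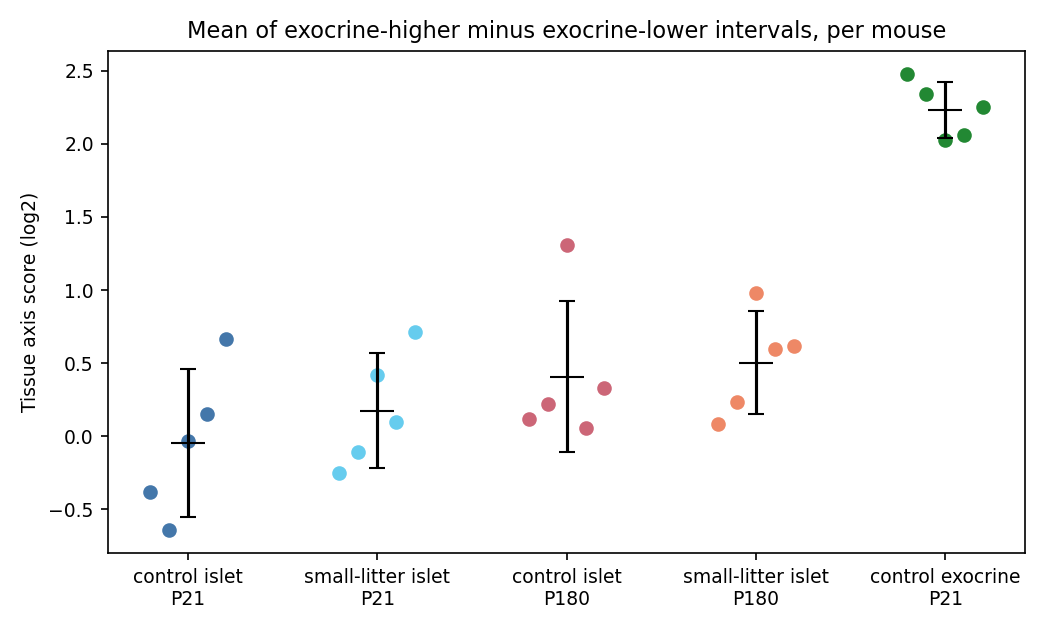
Tissue score of each library (log2, vertical axis) by group (horizontal axis), with the mean and SD of 5 mice per group. The 5 exocrine libraries lie between 2.03 and 2.48 and the 20 islet libraries between -0.64 and 1.31.

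The remaining comparisons asked whether litter size in suckling changed islet methylation. Counts of small-litter and control islets did not differ at any interval at P21 or at P180, and no interval had an age change that differed between the litter groups (0 of 22654 in each, edgeR quasi-likelihood test, adjusted p under 0.05). Unadjusted p-values under 0.05 were fewer than the 1133 expected, with 210 intervals at P21, 201 at P180 and 226 for the difference of the age changes. DESeq2 and limma voom with library weights also called 0 intervals in these comparisons, with 207 and 642 unadjusted p-values under 0.05 at P21 and 216 and 827 at P180. For the difference of the age changes they had 245 and 1249, the latter above the number expected. At chr11:94247192-94247996, small-litter and control islets had 5.40 and 5.93 CPM at P21 and 15.6 and 18.7 at P180. The tissue score of small-litter mice was 0.22 above that of control mice at P21 and 0.09 above it at P180, within the spread between mice (two-sided exact permutation p = 0.444 and p = 0.746, n = 5 per group), and at P21 the choice of intervals on the control libraries favours a higher score in small-litter mice. In simulated counts with the spread of these libraries, 48% of intervals changed 2-fold and 93% of those changed 4-fold between litter groups at P21 were recovered, or 39% and 90% with length trends added. In those simulations 5.60% of unadjusted p-values were under 0.05, or 8.80% with trends, against 0.927% in the data (edgeR). Small p-values were thus rarer in the data than in the simulations, so these recoveries may be too high. Intervals with low counts were not among those changed. Smaller differences were not simulated.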

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

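Intervals without a count were compared between libraries only after the libraries with many of them had been seen. In groups of 5 libraries, the gap of the most extreme library to its nearest neighbour was divided by the range of the group and compared with a critical value of 0.71. Of 103 groups compared in this way, 9 exceeded it, where about 5.15 are expected by chance, and 6 of the 9 concerned control P180 replicate 3.

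Control P180 replicate 3 stood above the other 4 mice of its group in the tissue score (1.31 against at most 0.33, ratio 0.780). It also stood above them at 5 of the intervals called for age: chr8:111345623-111346858 (27.5 CPM against at most 12.03, ratio 0.846), chr17:86723659-86724949 (38.3 against at most 15.3, ratio 0.803), chr4:154547184-154548292 (42.8 against at most 24.8, ratio 0.719), chr11:115865265-115866405 (33.1 against at most 21.3, ratio 0.742) and chr19:10305041-10305784 (212 against at most 136, ratio 0.927). Without this library 34 intervals were called for age, 32 of them among the 48.

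Small-litter P21 replicate 1 had 448 intervals without a count, where the other 4 mice of its group had 1 to 13 (ratio 0.973). Small-litter P180 replicate 2 had 205 such intervals against 7 to 19 (ratio 0.939). Exocrine replicate 1 had 7.11 CPM at chr19:3204050-3205811, where the other 4 exocrine libraries had 3.12 to 4.23 (ratio 0.723).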

How the results depend on the processing

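Length correction, voom weights, residual factors, the 3 libraries left out together, the admixture offset and the block within each age were chosen after seeing the data. The 48 age calls became 31 with library totals alone, 145 with DESeq2, 107 with length correction, 94 with voom weights, 1066 with 2 residual factors removed, 5 without the 3 libraries with most intervals at 0, 13 with an added 2-fold threshold and 0 with the admixture offset. In simulated counts with added length trends, 34.5% of age calls were false with residual factors removed, 18.2% with DESeq2 and 3.39% with length correction. Without trends 3.17% were false with residual factors removed and 13.2% with DESeq2. In the other settings 42 to 49 intervals were called. Leaving out 1 library at a time gave 16 to 50. Age in control mice alone, with 0 calls, had 16 with DESeq2, 2 with voom weights, 66 with residual factors removed and 0 to 1 with 1 library left out (1 without control P21 replicate 2). Age in small-litter mice had 45 with residual factors removed. The 4976 tissue calls became 9361 with residual factors removed and 2989 with the 2-fold threshold, and were 3578 to 6045 with 1 library left out. Litter size at both ages and the interaction stayed at 0 in each setting run. The share of intervals moving toward exocrine was 65.8 to 79.1 with 1 library left out, and the difference of the tissue score was 0.21 to 0.46. The cause was not tested except for the 2-fold threshold, which removes calls by its construction.

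Every named interval kept its direction in each setting that gave it an adjusted p, and some settings gave some intervals no value. Where they had a value, named tissue intervals also stayed past the threshold, in 197 refits with 1 library left out and 245 fits with other settings. Named age intervals did so in 207 refits and lost it in 33 with 1 library left out (15 at chr17:86723659-86724949, 9 at chr17:34793798-34794698, 4 at chr10:70323018-70323796, 3 at chr15:100525232-100526953 and 2 at chr10:61519325-61520904), and in 137 and 30 in other settings. Of these 30 losses, 12 came with the admixture offset, which no named age interval passed, 10 without the 3 libraries and 7 with the 2-fold threshold. The replicate numbers were not taken to pair the samples, since in no pair of groups did all 5 same-numbered pairs of libraries correlate above 0.1 in their deviations. Islets of the same age came closest, with 4 of 5 pairs at P180 (0.030 to 0.557) and 3 of 5 at P21 (-0.190 to 0.651) above 0.1, and 2 and 3 libraries correlated best with their own number, a hint from the data of something shared by number between the litter groups. With the replicate number as a block, 45 intervals were called for age and 3419 for tissue. With a block for each age and number, litter size at P21, at P180 and the interaction stayed at 0 calls, with 408, 572 and 557 unadjusted p-values under 0.05. Gene list tests and settings for normalized values were not run, since intervals were not assigned to genes and the values are counts. Low exocrine counts, and low islet counts at intervals higher in exocrine tissue, limit how precisely the largest differences between tissues are known.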

Other observations

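Tests of carried-over tissue with 1 share, of carry-over across litter groups, of shared libraries, of residual factors and of length for the share of increases, divisions with length correction, the block for each age and number, and divisions for comparisons with 0 calls, were chosen after results were seen. Differences between exocrine tissue and islets extended over neighbouring intervals. Of stretches of 3 or more adjoining intervals called in one direction, 33 were lower and 13 higher in exocrine tissue, the longest with 4 intervals. On chromosome 15 from 78755618 to 78757722 all 4 intervals were lower in exocrine tissue, with a median log2 fold change of -3.09, and on chromosome 2 from 116801826 to 116803140 all 3 were, with -3.28. On chromosome 15 from 78370414 to 78376252 all 3 were higher, with 1.72. Neighbouring pairs also rose together with age, chr1:189430670-189431030 with chr1:189431030-189431318 (log2 fold changes of 1.56 and 1.63) and chr10:79407570-79408489 with chr10:79408489-79409313 (0.74 and 0.76). These stretches and pairs were chosen after their values were seen. Adjoining intervals that share a restriction site had tissue changes that correlated with r = 0.475 over 5897 pairs (across intervals, which are not independent replicates), and 480 of the 520 pairs called at both members had the same direction. A shared site could raise both members, but neighbours within 5000 bp that share no site also correlated, with r = 0.203 over 1131 pairs, where pairs matched on length reached at most 0.128.

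Chromosomes differed in their share of calls in these libraries. The p-values given here count intervals as independent, although adjoining intervals correlated (r = 0.475) and all rest on the same 10 libraries. They are therefore too small and do not measure variation between mice. On X, 3.01% of the intervals were higher in exocrine tissue against 8.07% of all (adjusted p = 0.000645, Fisher's exact test, 40 tests), and with length correction 6.71% against 11.9% (adjusted p = 0.00402). The share of X intervals lower in exocrine tissue was 13.2% (adjusted p = 0.900), and 6.02% with length correction (adjusted p = 0.00238). On chromosome 7, 10.1% were higher (adjusted p = 0.0436), and 14.9% with length correction (adjusted p = 0.00238). On chromosome 9, 16.1% were lower (adjusted p = 0.275), and 15.4% with length correction (adjusted p = 0.00277).

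Other divisions of the libraries into groups of the same sizes were fitted, 100 per comparison with the true one included. For age, 1 division, the true one, reached the 48 calls and the highest other had 0, which argues against a random division as their source. With 100 divisions, 1 of 100 is the lowest share possible. Ages were shuffled separately within each litter group. Anything that libraries share by replicate number or litter of origin was therefore not kept and is not excluded. The 2167 intervals with an unadjusted p under 0.05 for age were reached by 11 of 100. The 4976 tissue calls were reached by 1 division, the true one, and the highest other had 789, which argues against a random division there too. For age in control mice, age in small-litter mice, litter size at P21, litter size at P180 and the interaction, a true count of 0 is reached by all 100 divisions whatever the data, so these counts say nothing about chance, with highest other counts of 1, 1, 685, 0 and 1. As many unadjusted p-values under 0.05 as in the true division were found in 32, 29, 95, 88 and 92 of 100. The 685 calls in 1 division of the P21 islet libraries, where the true one had 0, point to a structure of the samples beyond the groups.

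Age calls in islets ran toward the exocrine level, which exocrine tissue carried over into P180 islets could give, although islets were hand-picked. Deviations from a mixture of P21 islets and P21 exocrine tissue correlated between control and small-litter mice (r = 0.511 across intervals, 3 of 100 regroupings as high, 95th percentile 0.427, highest 0.677). That passed the bound set against carry-over as the whole cause, but cannot decide it. Exocrine tissue was measured at P21 only, and any change of it by P180 would give both litter groups the same deviations. An offset for the share ended all 48 calls, as the median absolute log2 fold change fell from 0.76 to 0.53 at an SE of 0.14. The offset takes out any movement of a library toward exocrine at exocrine-higher intervals, whatever its cause. The loss of calls therefore does not favour carry-over over a change of the islet cells. For the 100 strongest increases of control mice, the share needed in small-litter P180 mice was 43.8%. The share read from intervals over 4-fold higher in exocrine tissue was 2.19%, which is 41.6 percentage points lower (SE 4.23, 5 of 5 mice). The measures are unlike, since the needed share is a ratio of sums and the read share a median over intervals. From group means the gap was 40.78 points (one-sided exact p = 0.00397 over assignments of libraries to ages). That p is set against no age change, not against equal shares under carry-over. From exocrine-lower intervals the same mice read 34.2% (SE 13.7), so the size of the gap depends on the reading used. The needed share also rests on P21 exocrine levels, so this comparison does not decide against carry-over. Carry-over of 1 share per library cannot be told apart from other causes over all intervals, because the share from exocrine-lower intervals exceeded that from exocrine-higher ones by 32.1 points (SE 12.5), beyond 2 SE, but P21 mice of the same litter group ran from -78.8 to 81.0 (two-sided exact permutation p = 0.302). For tissue intervals as a whole, length bias cannot be told apart either, because 68.9% of them moved toward exocrine with length correction (highest other division, corrected alike, 76.6%, 13 of 100 as high). Of the 48 age calls, 46 stayed called with length correction, so it did not remove those calls. Noise of shared control libraries is argued against as the whole cause for the strongest increases. With these libraries divided, 1 of 100 regroupings of islets into ages had as many of 43 called higher in exocrine tissue as the true ages (25 to 31, highest regrouping 29). For tissue intervals as a whole, the 74.0% came from contrasts with no library in common, so shared libraries cannot have raised it. It lay within other divisions (highest 80.3%), which leaves chance open. A change of the islet cells with age stays open and untested.

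That 74.0% was reached by 9 of 100 divisions of the small-litter libraries, so chance cannot be excluded for it. The regroupings with divided control libraries were added after the counts for the true ages had been seen, and by sign alone 2 of 100 had as many of the 43 higher in exocrine tissue. A pair of further measures with no shared library was added after the 74.0% had been seen. Of the 100 strongest increases of small-litter mice 98 were tested for tissue and 87 of these (88.8%) were higher in exocrine tissue, reached by 1 of 100 divisions, the true one (highest other 86%), and of the 100 strongest decreases 95 were tested and 77 of these (81.1%) were lower, reached by 10 of 100 (highest other 95.9%). The comparison of needed shares across litter groups was added because the exocrine-lower readings spread widely, and its highest other assignment lay close below the true one, at 39.97 against 40.78 points from group means. The offset for admixture was redefined after its first result. The first form, from the mean of both shares, also left 0 calls, with a median absolute log2 fold change of 0.38. In control mice, whose P21 libraries also define the tissue contrast, the share read from exocrine-higher intervals was 15.2% at P180 and -1.25% at P21 (two-sided exact permutation p = 0.00794, n = 5). Choosing intervals that were low in these P21 libraries favours a higher share at P180, so this p may be too small. In small-litter mice, whose libraries did not enter that choice, the share was 2.19% and -2.73% (two-sided exact permutation p = 0.476, n = 5). From exocrine-lower intervals the ages differed by 39.6 points in control and 37.8 points in small-litter mice (two-sided exact permutation p = 0.373 and p = 0.294, n = 5).

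Increases chosen in one litter group were also followed in the other, with no library in common, a test chosen after the age calls were seen. Of the 100 strongest increases of control mice, 95 rose in small-litter mice (one-sided exact p = 0.0159), and of the 100 strongest of small-litter mice 95 rose in control mice (one-sided exact p = 0.0357). For decreases the counts were 93 and 90 (one-sided exact p = 0.00794 and p = 0.0119). The litter groups may not be independent, since deviations of same-numbered libraries correlated at up to 0.651 at P21 and 0.557 at P180. The assignments do not keep anything shared by number, so these p-values may be too small.

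Most age calls, 44 of 48 (91.7%), were increases, and the share was 76.2% with a mean of at least 50 counts, 68.3% with DESeq2 and 62.1% with 2 residual factors removed. It was 87.1% with library totals alone, above the bound of 60% set for this test, which argues against the scaling factors as the cause. Length bias cannot be told apart for this share, because with length correction it was 65.4% (SE 4.60), within 2 SE of that bound, and fell through decreases, which went from 4 to 37, while increases went from 44 to 70. Of the 48 calls, 46 stayed called with that correction. A change with age stays open and untested.

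Unadjusted p-values under 0.05 for litter size were fewer than expected in the edgeR fits. A lower depth of 1 litter group does not account for it, since median totals differed by at most 1.11 times at either age. Variation between libraries that groups do not explain may widen the spread: with 2 residual factors removed, the share of p-values under 0.05 at P21 rose 4.25 times, from 0.927% to 3.94%, with 0 calls. In simulated counts for litter size at P21 the share went from 5.60% to 5.72% on that removal without length trends, and from 8.80% to 14.2% with them, where 38.8% of calls were then false. A block for each age and replicate number raised the counts of small p-values from 210 to 408 at P21, from 201 to 572 at P180 and from 226 to 557 for the interaction, still below the 1133 expected and with 0 calls, and whether litter size has smaller effects stays open.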
